A study of Mus musculus with 6 samples.

How the data were processed

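Sorted pro-B and pre-B cells, pooled, from the bone marrow of old (24 months) and young (2 months) BALB/c mice were measured on 6 whole-transcript arrays, 3 per age group, from 100 ng of RNA each, per the labels. The deposited values are probe set intensities, summarised with RMA per the submitters' processing notes, whose version and settings are not given in the sources used here. They are linear, from 3.58 to 8502, so log2 was taken of the deposited intensity before any other step. Arrays were grouped by the age that the labels give, and the age groups were the single comparison. No array was left out of the comparison of 3 old with 3 young arrays.

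The table holds 28940 probe sets, of which 21789 are paired with 1 gene, 1621 with several and 5530 with none in the platform's annotation. The 23410 with a gene were tested. For 19938 genes with a probe set of their own, the gene is represented by the probe set with the highest mean, since 999 genes have more than 1. Differences were tested with limma 3.58.1 in R 4.3.3, with the age group as the only factor, moderated variances, a 2-sided test and the Benjamini-Hochberg adjustment. The threshold was an adjusted p under 0.05. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

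The design, the tests, 45 gene lists and a panel of 25 regulators and markers were written before the data were examined. The lists cover B cell stages, other bone marrow cell types, metabolism, the cell cycle, cytokine signalling, DNA repair and survival. The lists were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the 44 lists with at least 5 measured genes. The list of Xist and Y-linked genes, with 4 measured genes, was not tested. Of the listed genes 70 had no probe set of their own, among them Cdkn1a and Trp53 of the panel. Counts adjusted over the list alone use the same p-values with the adjustment made within the list. With 3 old and 3 young arrays 10966 of 23410 probe sets had an unadjusted p under 0.05 with limma. Such counts alone therefore do not set a list apart.

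Genes were named by a rule written before the data were examined. It takes called genes on single-gene probe sets without overlap between the groups, the 12 with the largest rise and the 12 with the largest fall, leaving out unnamed gene models and receptor genes. Where fewer than 5 were called in a direction, it fills up to 5 by the smallest unadjusted p. It adds every panel gene and, for each list described, up to 4 members with the smallest p in the direction of the list and up to 2 in the other.

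The groups share replicate numbers in the sample titles. The deviations from the group means of same-numbered arrays correlated at 0.157, 0.15 and 0.279 over the probe sets, all above the limit of 0.1. By that limit the numbers were treated as a possible pairing, in an alternative fit and in reading the splits, not in the main fit. Old replicate 1 correlated at 0.153 with young replicate 2 as well, and old replicate 2 at 0.141 with young replicate 1. The values therefore do not tell replicates 1 and 2 apart by number. A pairing is established neither by them nor by the labels. Fits with the replicate number as a block are given where they change a result.

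Alternatives fixed in advance were the replicate block, leaving out probe sets below the 30th percentile of mean level (4.19), testing all 28940 probe sets, centring each array on its median, quantile normalization, trended robust moderation, estimated array weights, leaving out each array in turn, adjusted p under 0.1, and thresholds with a 1.5-fold change. For lists they were an estimated correlation, the mean of all probe sets of a gene and the rotation test fry. Added after seeing the data were the fit of old replicate 3 alone against the young arrays with its own alternatives, and the comparison with random lists. For the latter, 10000 lists of equal size were drawn from genes matched on the young mean in 100 bins. Their genes were drawn singly, without the correlation between genes of a real list, so very low or high percentiles can be too extreme. The level of background was taken, also after seeing the data, from the 95th percentile of 1375 probe sets of olfactory and vomeronasal receptor genes on each array, since no detection calls were used. Where every value of 1 group lay within it, a change is given as at least the difference left after raising those values to that level, a bound chosen after seeing the data.

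The code was tested on simulated values for 23410 probe sets with 200 changed. Noise was drawn independently for each probe set, unlike the split among the old arrays that many genes share. The shares recovered therefore do not carry over to the data. For 3 old and 3 young arrays with the spread seen in each group, 0%, 12%, 50% and 68% of changes of 0.58, 1, 2 and 3 on the log2 scale were recovered, with 47 false calls. That is more false calls than an adjusted p under 0.05 should allow, so with unequal spread the error rate was not held. For 1 old and 3 young arrays with the spread of the young arrays these shares were 0%, 32%, 76% and 90%, with 3 false calls.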

Results

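Gene expression was measured in B cell progenitors, the bone marrow cells that assemble immunoglobulin genes before becoming mature B cells, from young and old BALB/c mice, an inbred laboratory strain. Pro-B and pre-B cells, the stages before and after the heavy chain gene is rearranged, were sorted and studied together without further treatment. There were 3 arrays from old mice at 24 months of age and 3 arrays from young mice at 2 months, each from 100 ng of RNA that was amplified and hybridised to a whole-transcript oligonucleotide array. Of the 28940 probe sets in the deposited table, 23410 were paired with at least 1 gene and were tested. All values are log2 of the deposited intensity, and differences are old minus young. The series concerns inflammation in aged animals and selection among B cell progenitors, and its single comparison asks how transcript levels in these cells differ between old and young mice. The sample names speak of separate mice, but whether an array holds 1 mouse or a pool is not stated, so p-values of genes measure only the spread between these arrays. The p-values of camera instead set the genes of a list against all others. They take the genes as almost independent, at the preset correlation of 0.01. The number of arrays limits the precision.

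In the comparison of all 3 old with all 3 young arrays, the regulators of B cell identity had lower means in the old group, but their values were split within that group and none passed the threshold. Ebf1, a transcription factor that specifies the B lineage, averaged 6.65 ± 2.69 (SD, n = 3) in the old group and 10 ± 0.09 (SD, n = 3) in the young group. Its values on old replicates 1, 2 and 3 were 4.64, 5.61 and 9.70. Il7r, the receptor for the cytokine that progenitors need to survive and divide, stood at 5.73, 6.30 and 10.08 on the old arrays against a young mean of 10.08 ± 0.10 (SD, n = 3). Rag1, which cuts DNA in immunoglobulin gene rearrangement, was at 5.51, 5.91 and 9.29 against 9.59 ± 0.18 (SD, n = 3). Mki67, a marker of dividing cells, was at 4.15, 5.45 and 9.55 against 9.88 ± 0.12 (SD, n = 3). On old replicates 1 and 2 all these genes lay within the level of background, so the sizes of their falls there are not measured. Vpreb1, part of the surrogate light chain, did not follow them and stood at 11.13, 11.69 and 10.82 against 10.99 ± 0.21 (SD, n = 3).

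Across the transcriptome the comparison called 0 probe sets with limma at an adjusted p under 0.05. The smallest adjusted p was 0.101, and 10966 probe sets had an unadjusted p under 0.05, of which 5830 were higher and 5136 lower in the old group. The 6 arrays could be parted without overlap at 59.0% of probe sets, where chance gives 10% for a single probe set. Whole arrays differed in signal, as given below, so probe sets are not independent. The excess over 10% is therefore no test of age. Leaving out old replicate 3 turned the count of called probe sets from 0 to 19285, and the fit with estimated array weights called 19998, whereas leaving out any other array left it at 0.

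The arrays themselves differed in signal. On old replicates 1 and 2 the interquartile range of log2 values was 1.41 and 1.40, against 2.44 on old replicate 3 and 2.80, 2.76 and 2.98 on young replicates 1 to 3. Among the 10% of probe sets brightest on the young arrays the median was 6.02 and 6.42 on old replicates 1 and 2, 9.04 on old replicate 3 and 9.22, 9.23 and 9.32 on the young arrays. Among the dimmest 10% it was 3.45 and 3.44 on old replicates 1 and 2, 2.85 on old replicate 3 and 2.78, 2.78 and 2.72 on the young arrays. Actb, a cytoskeletal gene that most cells express strongly, named here after its values were seen, was at 6.67, 6.84 and 11.65 on the old arrays and at 11.61, 11.58 and 11.59 on the young arrays. Not all bright genes fell. Rps12, a ribosomal protein gene also named afterwards, was at 11.35 and 11.85 on old replicates 1 and 2, by the brightest of its 14 probe sets. Its young mean was 11.78 ± 0.03 (SD, n = 3). Across probe sets, which are not independent replicates, old replicates 1 and 2 correlated with the young arrays at r from 0.607 to 0.702 and with each other at 0.894. Old replicate 3 correlated with the young arrays at r from 0.978 to 0.985, and the young arrays with each other at 0.993 to 0.996. Olfactory and vomeronasal receptor genes, which these cells are not known to use, gave 1375 probe sets, and 3398 and 3060 probe sets of all genes lay above their 95th percentile on old replicates 1 and 2. The number above it was 10686 on old replicate 3 and 12061, 11956 and 13021 on the young arrays.

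**Figure D1:**
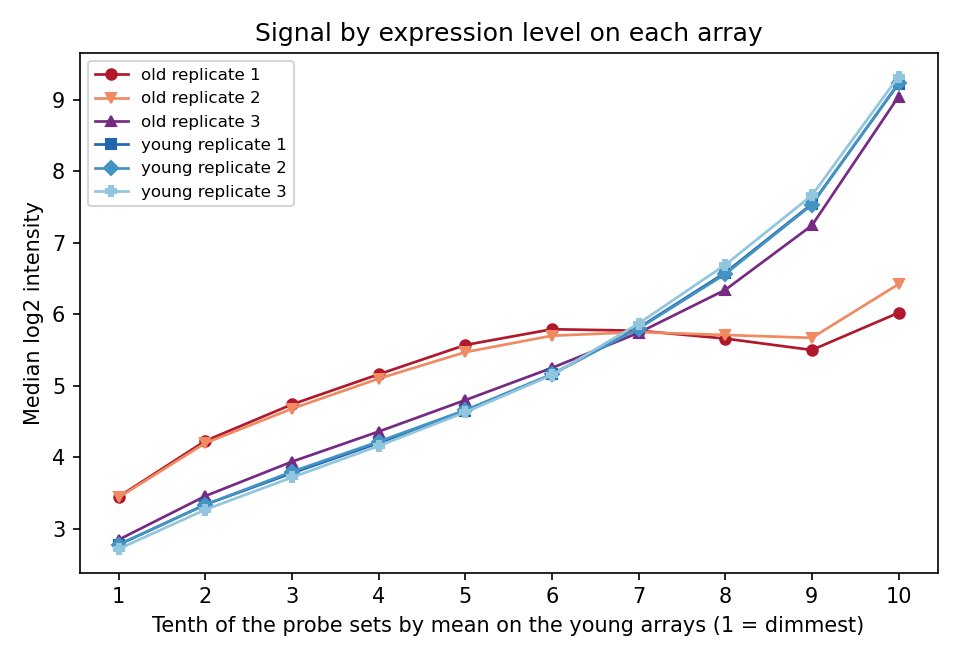
Median log2 intensity (y axis) in each 10% of the 23410 tested probe sets, ordered by their mean on the young arrays (x axis, 1 the dimmest and 10 the brightest), with a line for each of the 6 arrays. The lines of old replicates 1 and 2 are flatter, from 3.45 and 3.44 to 6.02 and 6.42, while old replicate 3 runs from 2.85 to 9.04, close to the young arrays.

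The genes with the smallest p in this comparison, chosen by the rule because no gene was called, had 3 old arrays on the same side of all 3 young arrays. None passed the threshold, each at an adjusted p of 0.101 with limma. On old replicates 1, 2 and 3, 48, 38 and 167 of 249 list members named by the rule lay above the receptor level, against 184, 187 and 201 on the young arrays. On the lower side stood Trim32, a ubiquitin ligase (difference -2.01 ± 0.27, SE), Bst1 (-1.64 ± 0.22, SE), Pdrg1, Fam72a and Zdhhc21, a palmitoyltransferase. Bst1, also called BP-3, is a surface antigen of early B cells, and it averaged 6.01 ± 0.24 (SD, n = 3) in the old and 7.64 ± 0.13 (SD, n = 3) in the young group. On the higher side stood Nlrc5, the transactivator of MHC class I genes (1.96 ± 0.32, SE), Eif4e1b (1.85 ± 0.29, SE), Jph2 (1.35 ± 0.21, SE), Krtap31-2 and Rny1, a small noncoding RNA. The Nlrc5 value is that of the brightest of its 19 probe sets. This probe set averaged 9.98 ± 0.58 (SD, n = 3) in the old and 8.02 ± 0.15 (SD, n = 3) in the young group. Eif4e1b and Jph2 have 2 probe sets each and are given by the brighter. No change of these genes as a whole is read from these values. Rny1 and Krtap31-2 were within the range of the receptor probe sets on all 6 arrays, so no size of change is given for them. Pdrg1, Fam72a and Zdhhc21 were within it on all 3 old arrays, so that their differences have only a bound, of at least 0.64, 0.33 and 0.84 lower on the log2 scale when the old values are raised to the receptor level. Trim32 and Bst1 were within it on old replicates 1 and 2, so the sizes given for them rest partly on values not above background.

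Of the 44 gene lists tested, 23 were lower in the old group by limma's camera with its preset correlation, and 0 were higher. All 23 calls were lost with an estimated correlation (adjusted p = 0.437 to 0.627). List medians are given relative to the median of all genes, which was 0.37. The B lineage identity list lay at -2.38 (adjusted p = 1.82e-07) and the pre-B stage list at -2.78 (adjusted p = 9.93e-06). The list of pre-B cell receptor signalling lay at -2.37 (adjusted p = 2.06e-06) and the pro-B stage list at -1.53 (adjusted p = 0.00343). Of 22 B lineage genes 22 had lower old means, as had 14 of 14 pre-B stage genes and 17 of 17 receptor signalling genes, yet 0 of them passed the threshold, over all genes or adjusted over the list alone. Of 15 pro-B stage genes 10 had lower old means, and 2 passed when adjusted over the list alone. By size of unadjusted p the B lineage list was led by Bcl11a (-0.97 ± 0.27, SE) and Blnk (-2.93 ± 0.98, SE). The pre-B stage list was led by Enpep (-1.27 ± 0.37, SE), the signalling list by Vav1 (-2.01 ± 0.65, SE), and the pro-B list, after Bst1, by Lef1 (-1.57 ± 0.32, SE). The mature B list, which holds MHC class II and homing genes, lay at -1 (adjusted p = 0.0144), and the neutrophil and granule list, a marker set of another bone marrow cell type, at -1.60 (adjusted p = 0.000166), with 0 of 20 and 6 of 23 genes lower when adjusted over the list alone. After quantile normalization the pro-B and mature B lists were not called (adjusted p = 0.24 and 0.813), nor were they without dim probe sets (adjusted p = 0.0583 and 0.102), or the mature B list without old replicate 2 (adjusted p = 0.0687). On old replicates 1 and 2 alone the B lineage list differed from the young mean by -2.86 and -3.18 in the median, and on old replicate 3 by -0.05. Among 10000 random lists matched on young expression level, the B lineage, pre-B, signalling and pro-B lists stood at the 48.88, 5.89, 6.68 and 42.38 percentiles.

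Lists of DNA copying, cell division and repair were called lower. DNA replication lay at -1.89 relative to all genes (adjusted p = 9.27e-14), mitosis at -2.38 (adjusted p = 5.32e-12), homologous recombination at -1.38 (adjusted p = 1.50e-06) and V(D)J recombination and end joining at -2.18 (adjusted p = 1.20e-05). Each stood at adjusted p = 0.437 with an estimated correlation. Adjusted over the list alone, 35 of 39 replication genes and 30 of 31 mitosis genes passed the threshold. So did 11 of 19 homologous recombination genes and 10 of 13 V(D)J recombination genes. All of these were lower, while 0 passed over all genes. Of the 4817 probe sets with a young mean above 7, however, 89.1% and 84.3% lay more than 1 log2 lower on old replicates 1 and 2. Such counts alone therefore do not set a list of bright genes apart. Among random lists matched on young expression level, the 4 lists stood at the 14.37, 9.93, 7.95 and 1.56 percentiles. On old replicates 1, 2 and 3 the replication list differed from the young mean by -2.08, -2.24 and -0.56 in the median. Pole2, a subunit of the leading-strand polymerase, differed by -1.49 ± 0.26 (SE), Gins2 by -2.05 ± 0.38 (SE) and the checkpoint kinase Chek1 by -1.92 ± 0.32 (SE). Histone genes lay at -1.07 (adjusted p = 0.00227), with 0 of 36 past the threshold in either adjustment (adjusted p = 0.543 for the list with an estimated correlation).

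Of 8 metabolic lists 7 were called lower, and one-carbon and folate metabolism was not (adjusted p = 0.0719), with 4 genes lower and 1 higher of 10 when adjusted over the list alone. It was called lower without old replicate 1 (adjusted p = 0.0483) and without young replicate 2 (0.046). De novo purine synthesis lay at -1.71 relative to all genes (adjusted p = 0.000407), purine salvage and breakdown at -1.08 (adjusted p = 0.0121), and pyrimidine and dNTP synthesis at -1.39 (adjusted p = 4.92e-05). The TCA cycle lay at -1.99 (adjusted p = 1.50e-06), oxidative phosphorylation at -1.84 (adjusted p = 2.09e-12), glycolysis at -0.84 (adjusted p = 0.0347) and antioxidant genes at -1.46 (adjusted p = 0.000612). These 7 lists stood at adjusted p = 0.437 with an estimated correlation. Adjusted over the list alone, 8 of 12 de novo purine genes, 4 of 13 salvage genes, 6 of 17 pyrimidine genes, 14 of 16 TCA cycle genes and 1 of 73 oxidative phosphorylation genes passed, all lower, and 0 of the glycolysis and antioxidant genes did. Atic, which closes the purine ring, differed by -1.22 ± 0.29 (SE), Idh3a by -0.99 ± 0.22 (SE) and Ndufv1, a subunit of respiratory complex I, by -1.50 ± 0.24 (SE). Of the lists on protein supply, the proteasome lay at -2.40 (adjusted p = 5.79e-12, 35 of 39 genes lower when adjusted over the list alone) and ribosomal proteins at -1.79 (adjusted p = 1.75e-10, 0 of 53). Myc targets and ribosome biogenesis lay at -1.53 (adjusted p = 1.79e-07, 10 of 25) and the unfolded protein response at -1.76 (adjusted p = 0.000736, 0 of 18). With an estimated correlation the ribosomal proteins stood at adjusted p = 0.468 and the others at 0.437. Old replicates 1 and 2 carried these falls, oxidative phosphorylation differing from the young mean by -2.15 and -2.09 there and by -0.19 on old replicate 3. Among random lists of matched level oxidative phosphorylation stood at the 99.99 percentile and ribosomal proteins at 100. By the brightest probe set of each gene, both thus fell less than genes of their level. Myc targets stood at 97.29, de novo purine synthesis at 48.61, purine salvage at 6.49, pyrimidine synthesis at 70.41, glycolysis at 74.82, the TCA cycle at 67.41, antioxidant genes at 47.33, the proteasome at 24.78 and the unfolded protein response at 53.93. The glycolysis call was lost with the replicate number as a block (adjusted p = 0.0546), with trended robust moderation (0.0893) and without old replicate 2 (0.0687), old replicate 3 (0.066), young replicate 1 (0.0512) or young replicate 3 (0.0639). After quantile normalization the calls of glycolysis (adjusted p = 0.421), oxidative phosphorylation (0.0633), Myc targets (0.422) and the unfolded protein response (0.0633) were lost, and without dim probe sets those of glycolysis (0.23) and purine salvage (0.11).

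Lists of inflammation lay below the median of all genes, and only the receptors of inflammatory cytokines were called. Among random lists of matched level those cytokine receptors stood at the 53.49 percentile. The NF-kB, type I interferon and interferon gamma lists stood at 52.13, 4.09 and 50.98. All lay within the range of genes of their level. The NF-kB and inflammatory list, with cytokines and feedback genes of that pathway, lay at -0.11 relative to all genes (adjusted p = 0.95). The type I interferon list lay at -0.34 (adjusted p = 0.474) and the list of interferon gamma and MHC class I genes at -0.79 (adjusted p = 0.111). In the latter 1 of 18 genes passed the threshold when adjusted over the list alone, Nlrc5, higher by its brightest probe set. This last list was called lower with array weights (adjusted p = 0.0331) and without old replicate 3 (0.046). Receptors of inflammatory cytokines were called lower at -0.80 (adjusted p = 0.033), led by Il10rb (-0.79 ± 0.23, SE) and Ifnar1 (-0.72 ± 0.22, SE), with 0 of 17 genes past the threshold, a call lost with an estimated correlation (adjusted p = 0.437), after quantile normalization (0.283), without dim probe sets (0.242) and without young replicate 3 (0.0559). Of the panel cytokines, Tnf averaged 5.32 ± 0.44 (SD, n = 3) in the old and 4.62 ± 0.03 (SD, n = 3) in the young group and Il1b 5.14 ± 0.65 (SD, n = 3) and 4.53 ± 0.27 (SD, n = 3), neither past the threshold (adjusted p = 0.101 and 0.19 with limma). Both lay within the range of the receptor probe sets on 5 of 6 arrays. The lists of p53 targets (adjusted p = 0.288), the BCL2 family (adjusted p = 0.838) and IL-7 receptor and STAT5 signalling (adjusted p = 0.401) were not called. The 21 uncalled lists had adjusted p from 0.0719 to 0.95. Of these, T cell genes were called higher without dim probe sets (adjusted p = 0.0307) and without young replicate 3 (0.025), and megakaryocyte and platelet genes without dim probe sets (0.0372). The rotation test fry, which asks whether the genes of a list move 1 way on balance, called 0 lists at a smallest adjusted p of 0.152.

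Of the 25 genes of a panel of B cell progenitor regulators, 23 had a probe set of their own, and 0 passed the threshold, over all genes or adjusted over the list alone. With the replicate number as a block, 9 passed when adjusted over the list alone and 0 over all genes. The largest differences after Mki67 (-3.50 ± 1.26, SE) and Ebf1 (-3.35 ± 1.21, SE) were those of Il7r (-2.71 ± 1.06, SE), Rag1 (-2.69 ± 0.94, SE), Ikzf1 (-2.57 ± 0.99, SE) and Pax5 (-2.07 ± 0.90, SE), each with old replicate 3 near the young arrays. Rag2 differed by -1.70 ± 0.52 (SE) and Foxo1 by -1.66 ± 0.61 (SE). Myc differed by -1.35 ± 0.31 (SE), Igll1 by -1.17 ± 0.47 (SE), Ccnd3 by -0.90 ± 0.36 (SE) and Tcf3 by -0.86 ± 0.48 (SE). Ccnd2, Stat5a, Stat5b and Bcl2 differed by -0.24, 0.08, 0.02 and -0.15. On old replicates 1 and 2 these panel genes lay within the range of the receptor probe sets, apart from Igll1 and Ccnd2. Pax5 was above it on old replicate 1. The sizes and the order of these differences therefore rest partly on values not above background. Dntt, which adds nucleotides at heavy chain junctions, the pro-apoptotic Bcl2l11 and Kit were within the range of the receptor probe sets on all 3 old arrays. With the old values raised to the receptor level Dntt was at least 1.19 lower, while for Bcl2l11 and Kit no bound is left. Cdkn2a, an inhibitor of division linked to ageing, was within the range of the receptor probe sets on all 6 arrays.

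**Figure D2:**
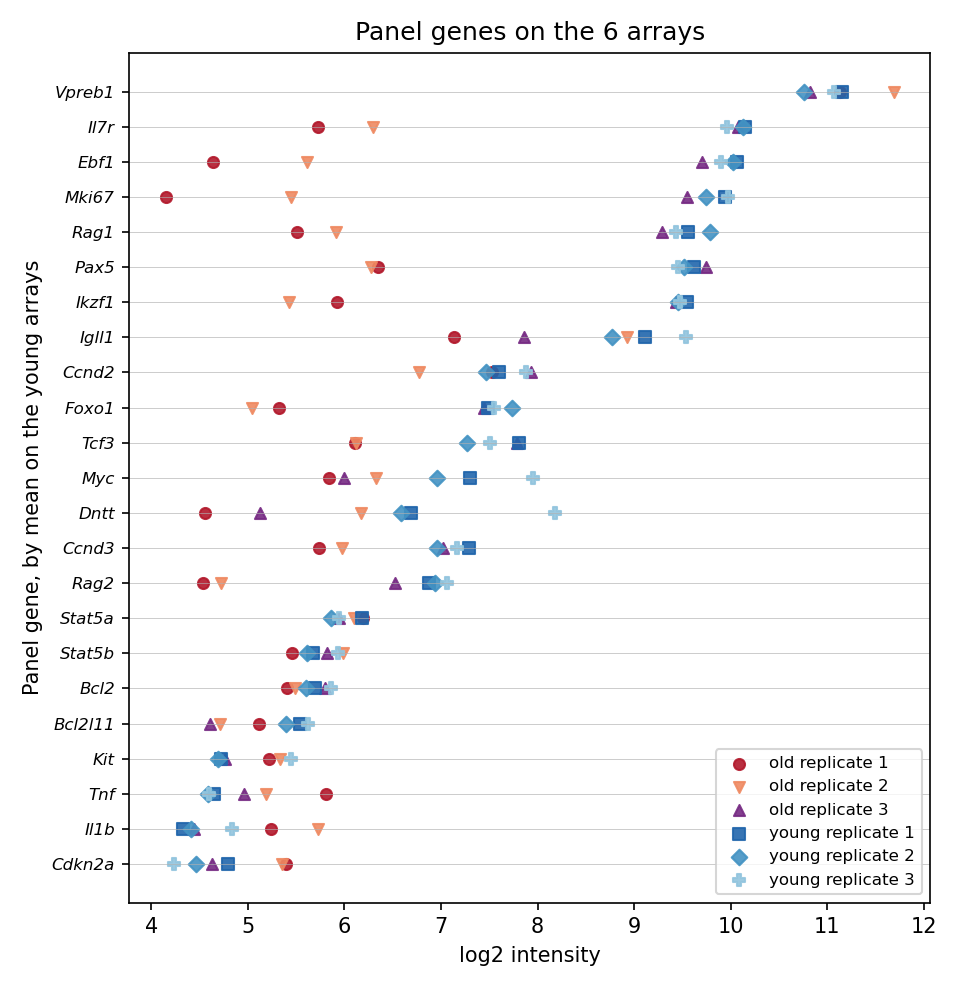
Log2 intensity (x axis) of the 23 panel genes (y axis, ordered by their mean on the young arrays), with a point for each of the 6 arrays. For Ebf1, Il7r, Rag1 and Mki67 old replicates 1 and 2 lie between 4.15 and 6.30 while old replicate 3 and the young arrays lie above 9, and for Dntt, Myc and Bcl2l11 all 3 old arrays lie below the young arrays.

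Because old replicates 1 and 2 stood apart, old replicate 3 was also set alone against the 3 young arrays, a comparison chosen after seeing the data. Here the lone array is assumed to vary like the young ones, and nothing checks whether another old mouse would give the same values. Pro-B and pre-B cells were sorted together, so levels within cells and the share of each stage cannot be told apart. Of 22 B lineage identity genes 1 passed the threshold, the transcription factor Bcl11a, 1.54-fold lower (adjusted p = 0.0394 with limma). Its call was lost after quantile normalization (adjusted p = 0.126) and without young replicate 1 or 2 (0.0886 and 0.0837). Among other regulators of B cell identity, old replicate 3 differed from the young mean by -0.01 ± 0.14 (SE) for Il7r, -0.29 ± 0.13 (SE) for Ebf1, 0.22 ± 0.13 (SE) for Pax5, -0.06 ± 0.13 (SE) for Ikzf1 and -0.30 ± 0.17 (SE) for Rag1, none past the threshold. Some early-stage genes were lower, while Vpreb1 (-0.17 ± 0.17, SE) did not pass the threshold. Igll1, the other part of the surrogate light chain, was 2.43-fold lower (adjusted p = 0.0346 with limma), Bst1 2.59-fold (adjusted p = 0.00817) and Lef1, a transcription factor of pro-B cells, 2.26-fold (adjusted p = 0.0429). Dntt, at least 3.92-fold lower from an old value within the range of the receptor probe sets, and Erg at -1.64 ± 0.40 (SE) missed the threshold (adjusted p = 0.0665 and 0.054). Without young replicate 3 both passed it (adjusted p = 1.95e-05 and 0.000114), and Erg also without young replicate 2 (0.0361). Of 15 pro-B stage genes 3 were lower over all genes and 5 adjusted over the list alone, and the list was called lower at -0.24 relative to all genes (adjusted p = 0.0355). Among random lists of matched level it stood at the 36.58 percentile, no lower than genes of its level. Its call was lost with an estimated correlation (adjusted p = 0.886). It was also lost after quantile normalization (adjusted p = 0.219) and without dim probe sets (0.184), as was that of Lef1 (0.0808 and 0.0504), which without young replicate 1 stood at 0.0947. The pre-B stage list and the B lineage identity list were not called. Among random lists of matched level they stood at the 98.58 and 99.8 percentiles, higher than genes of their level.

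This comparison called 1638 of 23410 probe sets with limma, 411 higher and 1227 lower. Over genes of matched level, and with different young arrays subtracted, the deviations of old replicate 3 correlated at r = 0.36 with those of old replicates 1 and 2, so the calls can hold a part shared with those arrays. Nearly all called probe sets lay on the same side of the young mean on both of those arrays. The same young mean is subtracted there, which by itself favours a shared side. After quantile normalization it called 955, 382 higher and 573 lower. Without young replicate 1, 2 or 3 it called 189, 927 and 3920. Genes named among the falls were Bcap29 (3.56-fold lower), Trim32 (3.40-fold), Gnrh1 (3.32-fold), Timm21 (3.11-fold), Rmnd5a (3.00-fold) and Fam136a (2.98-fold). For 6 others the value on old replicate 3 lay within the range of the receptor probe sets and the fall has only a bound, with that value raised to the receptor level. These were Car1, a carbonic anhydrase of red cell precursors (at least 3.33-fold), Zdhhc21 (at least 3.09-fold), Pdrg1 (at least 2.68-fold), Parpbp (at least 2.55-fold), Zfand4 (at least 1.79-fold) and Rnf170 (at least 1.24-fold). Among the rises were Hamp, the iron hormone hepcidin (at least 4.17-fold higher, the young values being within that range), Rpph1, the RNA of ribonuclease P (3.81-fold), Eif4e1b (2.43-fold), Jph2 (2.24-fold), Svs3a (at least 1.44-fold, for the same reason), and Stox2 and Rny1, both within that range on all 6 arrays. The rule also named Nlrc5 (2.47-fold), the chromatin remodeller Chd7 (2.32-fold), Tns1 and Vwa3b, whose probe sets did not move together. Of 19 Nlrc5 probe sets 3 were called higher and 2 lower, with a median difference of 0.17. Of 30 probe sets for Chd7, 6 for Tns1 and 8 for Vwa3b, 2, 1 and 1 were called higher. Of 2 probe sets each for Eif4e1b, Jph2 and Stox2, 1 was called, the others differing by 0.46, 0.14 and 0.14. For none of these 7 genes is a change of the gene as a whole read from them. The adjusted p of the genes named so far ran from 0.00106 to 0.0423. A Kcnma1 probe set rose at least 169-fold from young values within the receptor range, at 4.47, 8.58 and 12.15 on the old arrays and 3.62, 3.98 and 3.67 on the young arrays. Another Kcnma1 probe set was at 3.46 on old replicate 3 and between 3.39 and 3.52 on the young arrays. Without young replicate 1, the calls of Chd7, Vwa3b, Fam136a and Zfand4 were lost (adjusted p = 0.0721, 0.0603, 0.0712 and 0.0656), and without young replicate 2 that of Chd7 (adjusted p = 0.0663).

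DNA replication and repair genes were lower on old replicate 3. All gene lists here are again relative to the all-gene median, which was 0.04. Of 39 replication genes 39 were below the young mean, 8 passed the threshold over all genes and 22 when adjusted over the list alone. The list was called at -0.61 relative to all genes (adjusted p = 4.16e-12). It and the other lists of this paragraph stood at adjusted p = 0.886 with an estimated correlation. Prim1, which makes the primers of DNA synthesis, was 2.64-fold lower (adjusted p = 0.0182), Gins2 2.36-fold (adjusted p = 0.0182), Pole2 2.11-fold (adjusted p = 0.0168) and Rpa3 -0.92 ± 0.14 (SE, adjusted p = 0.0178) with limma. The mitosis list was called at -0.55 (adjusted p = 3.18e-09), with 4 of 31 genes lower over all genes and 17 adjusted over the list alone. Among them were Bub1 (-0.95 ± 0.18, SE), Anln (-0.94 ± 0.19, SE), Ccnb2 (-0.68 ± 0.14, SE) and Cenpa (-0.66 ± 0.13, SE). Mki67 itself was at -0.33 ± 0.14 (SE) and did not pass (adjusted p = 0.183). Homologous recombination was called at -0.60 (adjusted p = 6.47e-06), with 5 of 19 genes lower over all genes and 9 adjusted over the list alone. Chek1 was 2.40-fold lower (adjusted p = 0.0105), and Rad54b differed by -1.06. The values of Fancd2 and Palb2 on old replicate 3 were within the range of the receptor probe sets, which leaves Fancd2 at least 0.88 lower on the log2 scale and Palb2 without a bound. V(D)J recombination and end joining was called at -0.48 (adjusted p = 0.000281), with Hmgb1, Xrcc5 and Atm past the threshold of 13 genes, and 7 when adjusted over the list alone. The replication, mitosis and homologous recombination lists lay at the 0.00, 0.17 and 0.10 percentiles of 10000 random lists matched on young expression level, and the V(D)J list at the 4.46 percentile. All 4 list calls were kept after quantile normalization, without dim probe sets and without each young array. Of the called genes named here, only Chek1 and Hmgb1 stayed past the threshold without young replicate 1, the others standing at adjusted p from 0.0603 to 0.1. Bub1, Anln, Ccnb2, Cenpa and Atm did not pass after quantile normalization (adjusted p = 0.0538 to 0.133), nor Ccnb2 and Cenpa without young replicate 2 (0.054 and 0.0556).

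Lists of nucleotide synthesis, one-carbon metabolism, the proteasome, Myc targets and antioxidant genes were called lower too, most of their genes not passing the threshold over all genes. All these lists stood at adjusted p = 0.886 with an estimated correlation. Pyrimidine and dNTP synthesis was called at -0.50 relative to all genes (adjusted p = 8.74e-05), with Nme1, Nme2, Dtymk and Tk1 among 17 genes lower over all genes and 6 adjusted over the list alone. De novo purine synthesis was called at -0.48 (adjusted p = 0.00365), with Gmps (-0.76 ± 0.18, SE) and Prps1 (-0.74 ± 0.16, SE) lower of 12 genes and 6 adjusted over the list alone. Purine salvage lay at -0.31 (adjusted p = 0.0148, 2 of 13 lower and 3 adjusted over the list alone) and one-carbon and folate metabolism at -0.43 (adjusted p = 0.0355, 1 of 10 and 2 alone). The proteasome was called at -0.45 (adjusted p = 5.65e-12), with 13 of 39 genes lower over all genes and 21 adjusted over the list alone. It was led by Psmb4, 2.67-fold lower (adjusted p = 0.00565). Myc targets and ribosome biogenesis were called at -0.44 (adjusted p = 8.77e-06, 7 of 25 lower and 12 adjusted over the list alone), among them Cdk4 and Dkc1. Myc itself was 2.65-fold lower (adjusted p = 0.0468). Antioxidant genes were called at -0.42 (adjusted p = 0.00026), with Gpx1 (-1.28 ± 0.14, SE) and Prdx3 (-0.82 ± 0.18, SE) lower of 17 in both adjustments. Ribosomal proteins were not called at -0.01 (adjusted p = 0.941). Among random lists of matched level, the proteasome stood at the 0.18 percentile, antioxidant genes at 0.50, pyrimidine synthesis at 1.73, de novo purine synthesis at 3.07, one-carbon metabolism at 3.34, Myc targets at 3.6 and purine salvage at 7.29. The last 4 lie above the 2.5 percentile, within the range of genes of their level. The TCA cycle (-0.33, adjusted p = 0.000281, 1 of 16 genes lower and 5 adjusted over the list alone) and oxidative phosphorylation (-0.23, adjusted p = 8.74e-05, 5 of 73 lower, and 14 lower and 1 higher over the list alone) were called too, but stood at the 46.74 and 65.19 percentiles. After quantile normalization the calls of these lists (adjusted p = 0.314 and 0.761), de novo purine synthesis (0.0892), purine salvage (0.0543) and one-carbon metabolism (0.13) were lost. The last 2 were also lost without dim probe sets (0.0945 and 0.172) and without young replicate 3 (0.0588 and 0.1). Psmb4 and Gpx1 stayed past the threshold without young replicate 1, the other genes named here standing at adjusted p from 0.0615 to 0.121. After quantile normalization Psmb4, Gpx1, Nme2 and Dkc1 stayed past it. Without young replicate 2 the calls of Nme1, Gmps, Prps1 and Prdx3 were lost (adjusted p = 0.0547, 0.0673, 0.0562 and 0.0703), and without dim probe sets those of Tk1 and Gmps (0.0526 and 0.0525).

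Survival and inflammation genes gave few calls on old replicate 3. Among these calls were Il10rb of the inflammatory cytokine receptors and Ei24 and Rrm2b of the p53 targets, all lower. Of these genes only Ei24 stayed called in every alternative. Bcl2l11 was at least 1.26-fold lower (adjusted p = 0.0182), its value on old replicate 3 lying within the range of the receptor probe sets. With Igll1 and Myc it made 3 called panel genes of 23, or 4 with Dntt when adjusted over the list alone. The calls of Igll1 and Myc were lost after quantile normalization (adjusted p = 0.0702 and 0.075), that of Myc with trended robust moderation and without dim probe sets (0.0734 and 0.0542), and those of all 3 without young replicate 1 (adjusted p = 0.0931, 0.103 and 0.0683). The NF-kB and inflammatory list lay at 0.01 relative to all genes (adjusted p = 0.562, 0 of 26 genes past the threshold) and the type I interferon list at -0.01 (adjusted p = 0.603, 0 of 31). In the list of interferon gamma and MHC class I genes (0.02, adjusted p = 0.562) 1 of 18 genes was called, on the Nlrc5 probe set above. Cd74, the invariant chain of MHC class II, was 1.84-fold higher (adjusted p = 0.0397) and H2-DMa 1.48-fold lower (adjusted p = 0.048). The mature B list as a whole lay at 0.11 (adjusted p = 0.328) and was called higher after quantile normalization and without young replicate 2 (adjusted p = 0.00387 and 0.0397). The calls of Cd74 and H2-DMa were lost without young replicate 1 (adjusted p = 0.0947 and 0.123). That of H2-DMa was also lost after quantile normalization (adjusted p = 0.137), with trended robust moderation (0.0508), without dim probe sets (0.052) and without young replicate 2 (0.104). The neutrophil and granule list was called lower at -0.39 (adjusted p = 0.0192), with Chil3 (-1.12 ± 0.25, SE) past the threshold, calls lost after quantile normalization (adjusted p = 0.0819 and 0.0874) and without dim probe sets (0.164 and 0.052). The list call was also lost with an estimated correlation (adjusted p = 0.886) and without young replicate 3 (0.0607), and that of Chil3 without young replicate 1 (0.107). The pre-B cell receptor signalling list was called at -0.16 (adjusted p = 0.0335), with 0 of 17 genes past it. It stood at the 95.93 percentile of random lists of matched level, within the range of genes of its level. Its call was lost with an estimated correlation (adjusted p = 0.886), without dim probe sets (0.179) and without young replicate 3 (0.0607), and its direction turned after quantile normalization (0.761). In all, 16 lists were called lower and 0 higher, the 28 others having adjusted p from 0.079 to 0.941. Quantile normalization gave 10 lower and 3 higher, the 3 being mature B, histones (adjusted p = 0.00387) and IL-7 receptor and STAT5 signalling (0.0349). Leaving out 1 young array called histones higher (without young replicate 3, adjusted p = 0.0157), immunoglobulin segments higher (without 2, 0.0483) and inflammatory cytokine receptors lower (without 1, 0.0368). All 16 calls were lost with an estimated correlation (adjusted p = 0.886).

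**Figure D3:**
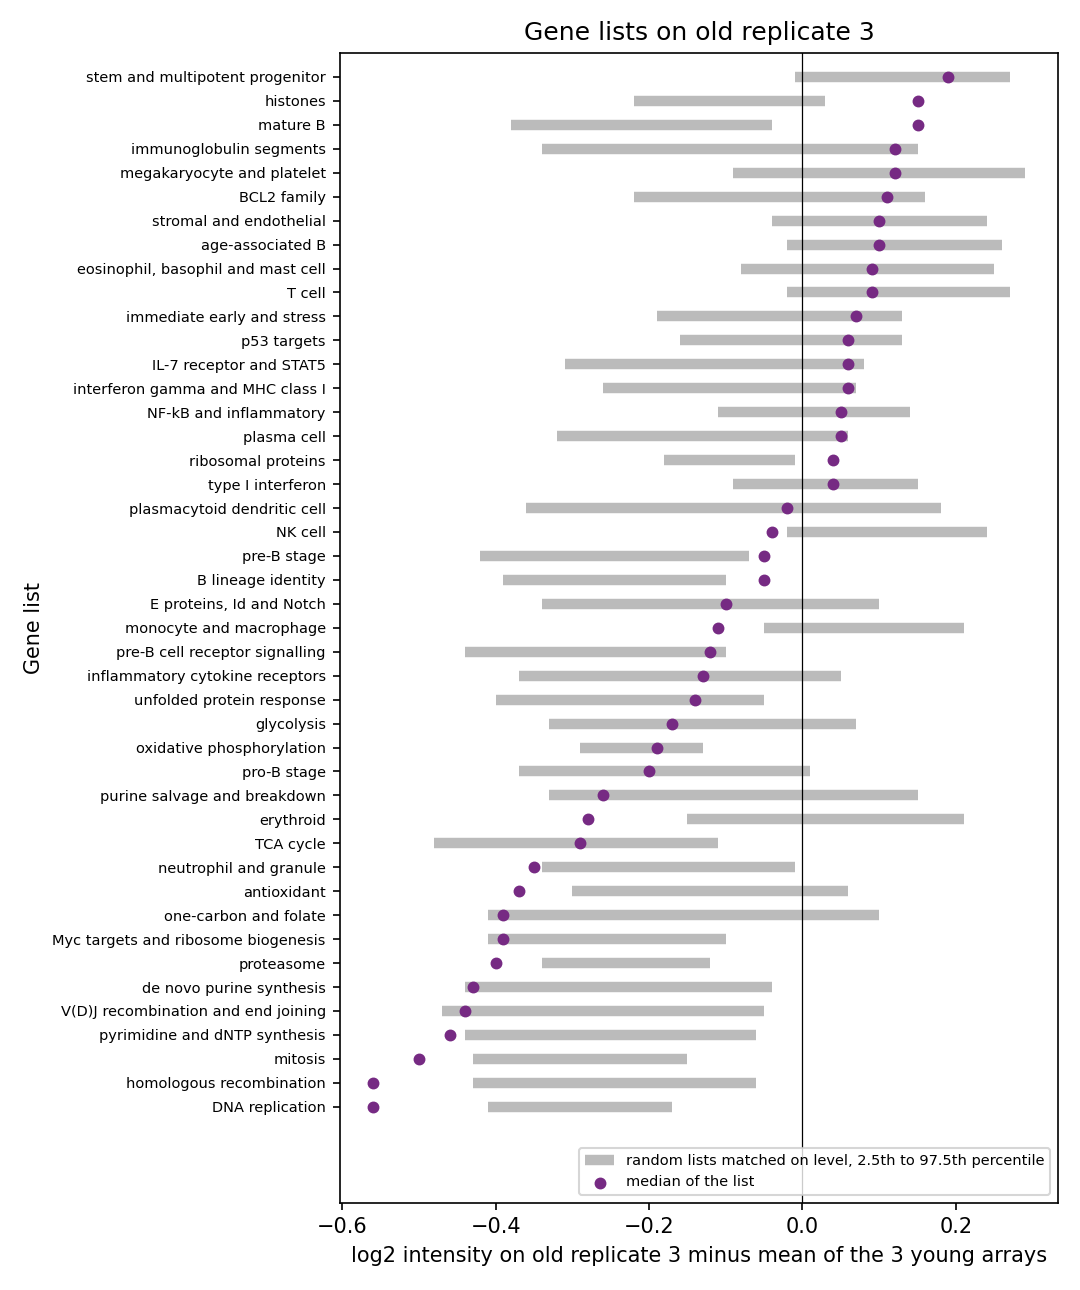
Median difference of each of the 44 tested gene lists between old replicate 3 and the mean of the 3 young arrays (x axis, log2 intensity; points), with the middle 95% of 10000 random lists matched on young expression level (grey bars). DNA replication and homologous recombination lie at -0.56, mitosis at -0.50 and the proteasome at -0.40, all below their bars, while histone and mature B genes lie at 0.15, above theirs. B lineage identity and pre-B stage genes at -0.05 and ribosomal proteins at 0.04 also lie above their bars.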

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

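The count of 0 called probe sets between 3 old and 3 young arrays became 19998 with array weights, 1638 with old replicate 3 alone against the young arrays (chosen after seeing the data) and 10715 at an unadjusted p under 0.05 with a 1.5-fold change, and ran from 0 to 19285 when leaving out each array in turn. Called panel genes went from 0 to 17 with array weights and 3 with old replicate 3 alone, and ran from 0 to 16 when leaving out each array. The array weights were 0.045 for old replicate 3 and 0.288 and 2.598 for old replicates 1 and 2, so the old group in that fit rests mostly on old replicate 2. The cause of the other moves was not tested. Called gene lists went from 23 to 0 with an estimated correlation and to 0 with fry, and kept between 21 and 24 when leaving out each array. With the dim probe sets left out 20 were called, 2 higher and 18 lower, and after quantile normalization 16, all lower.

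With the replicate number as a block, 0 probe sets and 0 panel genes were called, as without it, and 22 lists in place of 23. It changed no other call over all genes, while 9 panel genes passed when adjusted over the list alone, against 0 without it. Called probe sets between old replicate 3 and the young arrays went from 1638 to 955 after quantile normalization, 790 of them called in the same direction in both, and ran from 189 to 3920 when leaving out each young array. Called lists there went from 16 to 0 with an estimated correlation.

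The 10 genes named with 3 old arrays kept their direction in every alternative that measured them, as did the 24 named with old replicate 3 alone. Most of this was fixed in advance. Their values did not overlap between the arrays compared, so leaving out or weighting arrays could not turn a direction. Without dim probe sets 9 of the 10 and 21 of the 24 were measured. Of the 24, 24 stayed called after quantile normalization and 20 without young replicate 1. Some lists turned direction relative to all genes, or in the test, and the cause was not tested. After quantile normalization, mature B stood at -0.05 and glycolysis at 0.12 with 3 old arrays, and pre-B cell receptor signalling at 0.09 with old replicate 3 alone. With old replicate 3 alone, mature B stood at 0.11, ribosomal proteins at -0.01 and histones at 0.11. Leaving out list members called individually changed nothing in the comparison of 3 old with 3 young arrays, since none was called. On old replicates 1 and 2 the precision is limited by signal over background, with 3398 and 3060 probe sets above the receptor level against 10686 on old replicate 3.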

Other observations

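Some RNAs outside the lists of B cell function were also higher on old replicate 3, in the comparison chosen after seeing the data. Rpph1, the RNA component of ribonuclease P, stood at 10.89 against 8.96 ± 0.10 (SD, n = 3) on the young arrays, and at 9.05 and 8.47 on old replicates 1 and 2. Of 36 histone genes 25 were above the young mean, with H1f7 called higher (0.70 ± 0.13, SE) and H1f5 called lower (-0.92 ± 0.21, SE), although the list was not called. Among plasma cell genes Tnfrsf17, the receptor BCMA, was called higher (adjusted p = 0.0472), though within the range of the receptor probe sets on all 6 arrays, and Mzb1, an endoplasmic reticulum chaperone of B cells, lower (-0.96 ± 0.21, SE). Without young replicate 1 the calls of H1f7, H1f5, Tnfrsf17 and Mzb1 were lost, at adjusted p from 0.0762 to 0.113, and those of H1f5, Tnfrsf17 and Mzb1 also after quantile normalization (adjusted p = 0.109, 0.105 and 0.0969). Without young replicate 2 those of H1f7, Tnfrsf17 and Mzb1 were lost (adjusted p = 0.0627, 0.095 and 0.0542), and without dim probe sets that of H1f5 (0.0526). Of 411 probe sets called higher, 88 carried receptor or small RNA symbols, which make up 1833 of the 23410 tested.

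Markers of other marrow cells moved in different directions on the same array. Car1 was the called gene of 16 erythroid genes, 12 of which were below the young mean, and Ms4a6c (-0.99 ± 0.18, SE) that of 20 monocyte and macrophage genes. The call of Ms4a6c was lost without young replicate 1 (adjusted p = 0.0844). Adjusted over the list alone, Gata1 of the erythroid list, Cx3cr1 of the monocyte list and Col1a1 and Col1a2 of 13 stromal and endothelial genes were higher (0.51 ± 0.13, 0.53 ± 0.13, 0.50 ± 0.13 and 0.54 ± 0.15, SE). Lower in the same adjustment were Pecam1 of the stromal list (-0.42 ± 0.12, SE), Ms4a6c, and Car1 and Cldn13 of the erythroid list, both within the range of the receptor probe sets on old replicate 3. The erythroid and monocyte lists were not called, at -0.33 and -0.16 relative to all genes, but were called lower after quantile normalization (adjusted p = 0.0345 and 0.00732), the erythroid list also without young replicate 1 (0.00131) and the monocyte list without young replicate 2 (0.0434). Among random lists of matched level, the erythroid, monocyte, NK cell and neutrophil lists stood at the 0.17, 0.28, 1.00 and 2.28 percentiles, the first of them as low as the mitosis list. S100a8, a granule protein of neutrophils named after its values were seen, lay between 10.3 and 11.51 on all 6 arrays.

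The tests of this pattern, old replicates 1 and 2 standing apart, were chosen after the result was seen. Loss of signal on these arrays would flatten them, and the higher of their slopes on the young mean was 0.43, against 0.93 on old replicate 3, as such a loss would give. The flattening was not uniform, since Rps12 and Vpreb1 stayed near their young levels on both arrays. Another cell type should keep genes that all cells use, but the proteasome list was at -2.73 on the less affected array, which rules this out as the whole cause but not beneath a loss of signal. Their highest correlation with any young array was 0.702, but lost signal lowers a correlation whatever the label, so a wrong label beneath such a loss cannot be told apart from a right one. An effect of age on some mice only was not tested and stays open.

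The tests of the 23 lists that were lower in the comparison of 3 old with 3 young arrays were also chosen after the result was seen. If signal was lost in proportion to a gene's level, few of these lists should fall below random lists of matched level, and in the old mean 1 of 23 did, the list of V(D)J recombination. On old replicates 1, 2 and 3 alone 0, 4 and 7 did, the last 2 counts beyond the limit of 3 set for this cause, so such a loss cannot be told apart from other causes here. Among the 10 ways to split the 6 arrays 3 against 3, all 10 match the real count of 0 probe sets and 10 that of 0 panel genes by construction, which tells nothing. In 4 of them at least the 23 lists of the real split were called, with up to 25, each of the 4 holding old replicates 1 and 2 together. Of the splits that part all same-numbered arrays, as the real one does, the others called 23, 17 and 5 lists. With 10 splits the share can never be under 10%, so age and chance cannot be told apart this way.

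Of the tests of the lower replication, mitosis and homologous recombination lists on old replicate 3, only that of a gene-specific loss was written before its result was seen. Loss in proportion to level should place them among random lists of matched level, and the highest of their percentiles there was 0.17. The lists thus fell more than genes of their level drawn singly. How far genes that vary together would stray from their level was not tested, and the erythroid list stood at 0.17 too. Such a loss is therefore not excluded by these percentiles. After removing what old replicate 3 shares with old replicates 1 and 2, the highest percentile of the 3 lists was 1.11. A shared gene-specific loss cannot be told apart from age here. Only 12 and 10 of the 89 genes lie above background on those arrays, against 86 on old replicate 3. An admixture of mature B cells could lower them, and 15 of 20 mature B genes were higher, though Il7r (-0.01) and H2-Aa (-0.06) were unmoved and only Cd74 was called higher. An effect of age was not tested on this single array and stays open.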
